A study of Arabidopsis thaliana with 14 samples.

How the data were processed

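Whole Arabidopsis Col-0 seedlings were profiled on 14 Affymetrix ATH1 arrays, in 7 groups of 2 arrays. Seedlings were grown under 16 h of light and 8 h of dark at 22 °C and kept for 1 day in liquid 0.5x MS medium. On day 6 after germination they received 50 µM of compound 7606596 or of compound 5929745, both known here only by these code names. They were collected 3 h or 12 h later, beside untreated seedlings of the same times and untreated seedlings collected at 0 h. The labels do not say whether the untreated seedlings received the solvent of the compounds.

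Per the labels, the deposited values are MAS5 signals, with no version given. MAS5 corrects the background of each array, summarises the perfect match and mismatch probes of each probe set and scales each array on its own. The unit of the deposited values is therefore linear signal intensity, scaled by the authors; on every array the mean over the central 96% of probe sets was 499.8. Detection calls were not in the table, and nothing was pooled. Median signals ran from 151.9 to 168.6 over the arrays. Within a group, the log2 signals of the 2 arrays correlated across probe sets with r between 0.983 and 0.989, where probe sets are not independent replicates.

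Of 22810 probe sets, 64 controls were left out. The 15922 probe sets with a mean signal over all arrays at or above the 30th percentile (42.3) were kept. Signals were taken to log2 after adding 16 and fitted in R 4.3.3 with limma 3.58.1, with 1 mean for each group and an empirical Bayes variance that follows the mean signal (7 residual and 11.4 prior degrees of freedom). All tests were two-sided, and the p-values of each comparison were adjusted over the kept probe sets by the Benjamini-Hochberg method. A probe set was called at an adjusted p under 0.05. Errors beside signals are SD over 2 arrays, and errors beside log2 changes are standard errors of the fit. Log2 changes include the offset, so they are smaller than the ratio of the group means for weak signals. The number of arrays limits the precision.

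The annotation named a single gene for 13513 probe sets, of which 8738 were kept. It left 8730 probe sets without a gene and gave several genes for 503. Counts of probe sets cover all that were kept, and gene names cover those 8738. Many listed genes could therefore not be measured.

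Each compound was compared with the untreated seedlings of the same time and with the other compound at the same dose and time. The change of each effect between 3 h and 12 h was tested as an interaction. Untreated seedlings at 3 h and 12 h were compared with 0 h. After the signals of spike-in controls had been seen, 5 comparisons were added: each treated group with 0 h, and untreated seedlings at 12 h with those at 3 h. The replicate numbers were not used as a block in the main model.

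Gene lists were tested with limma's camera with a preset correlation between genes of 0.01, and again with an estimated correlation. Lists needed at least 3 measured members. Before the data were examined, 24 lists were fixed: chlorophyll synthesis, light-harvesting proteins, nuclear photosystem subunits, Calvin cycle, carotenoid and MEP pathway, plastid-encoded photosynthesis, plastid-encoded housekeeping, plastid transcription machinery, greening regulators, plastid protein import, plastid ribosomal proteins, xenobiotic detoxification, heat shock, reactive oxygen response, jasmonate, abscisic acid and drought, early auxin response, defence and salicylate, circadian clock, dark and sugar starvation, flavonoid and anthocyanin, cell cycle, hypoxia, and root tissue markers. A further 18 lists were drawn from the symbols in the annotation before any fold change was seen, and were adjusted as a separate family.

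Genes to be named were chosen by a rule fixed before the data were examined. It takes the 6 largest rises and the 6 largest falls per comparison (4 each for untreated seedlings over time) among called probe sets of a single gene. Both arrays of the higher group had to lie outside those of the lower group, and the higher group mean had to reach the median of the mean signals (168). It also takes up to 4 members with the smallest adjusted p from each fixed list that passed its test or had 3 called members. Of 11 genes fixed by name, 1 was named in the annotation and 0 were kept. The rule names 94 genes. Members of the 18 added lists are outside the rule.

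The fit was tested on simulated data in which 200 probe sets were changed in the comparison of 7606596 with untreated seedlings at 3 h. It recovered 29 of 67 probe sets changed 1.5-fold, 58 of 67 changed 2-fold and 66 of 66 changed 4-fold, with 11 false calls among 164. A shifted set of 20 genes had a camera p of 5.11e-26, and 34 of 1000 unshifted sets had p under 0.05. The simulated probe sets varied independently of each other, so this check does not cover lists whose genes vary together. Overlaps between the compounds were set against 100 simulations of unchanged groups that shared the untreated arrays, since 2 untreated arrays cannot be divided between 2 comparisons.

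The alternatives tried were quantile normalization, median scaling, offsets of 1 and 64, no filter and a filter at the 60th percentile, the replicate number as a block, only the groups of a comparison in the fit, no variance trend, each array left out in turn, an estimated correlation for lists and, added after the spike-in signals were seen, 0 h as the reference.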

Results

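Transcript levels were measured on ATH1 arrays in whole Arabidopsis Col-0 seedlings exposed for 3 h or 12 h to 50 µM of 1 of 2 code-named compounds, in a series whose title calls the chemical albino. The 14 arrays fall into 7 groups of 2: untreated seedlings at 0 h, 3 h and 12 h, and seedlings with 7606596 or with 5929745 at 3 h and 12 h. Values are MAS5 signals in linear units, and changes are log2 fold changes from limma. Poly-A spike-in transcripts, which are added to the RNA before labelling, separated the arrays in another way. On the 4 untreated arrays of 3 h and 12 h the 3' probe set of dap had a mean signal of 497 ± 48.9 (SD, n = 4), against 189 ± 24.1 (SD, n = 10) on the other 10, a ratio of 2.63, with no overlap between them. The 6 poly-A probe sets were higher there by 1.77 to 4.03 times, and the 25S rRNA probe set was lower, at 220 ± 40.1 against 489 ± 187. The 5' probe set of actin was 1.64 times as high there (624 ± 123 against 381 ± 63.9), and its 3' probe set 1.05 times. The hybridization controls bioD and cre had ratios of 0.939 and 1.04 with both times pooled. Over all hybridization controls the mean log2 signal was 10.17 and 10.23 on the untreated 12 h arrays, against 10.82 and 10.79 on those of 3 h. It was at least 10.54 on every other array, so comparisons with untreated 12 h seedlings cross this difference too. The untreated arrays of 0 h and all 8 treated arrays lay at the lower poly-A level. Each comparison of a compound with untreated seedlings of the same time therefore crosses these levels, as do those of untreated seedlings at 3 h and 12 h with 0 h. The arrays of the 2 compounds differed by 0.01 in mean log2 poly-A signal over both times and so lie within a level. They still differed in 25S rRNA at 3 h, with 850 and 760 for 5929745 against 531 and 466 for 7606596, while at 12 h the signals overlapped (290 and 338 against 409 and 320).

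**Figure D1:**
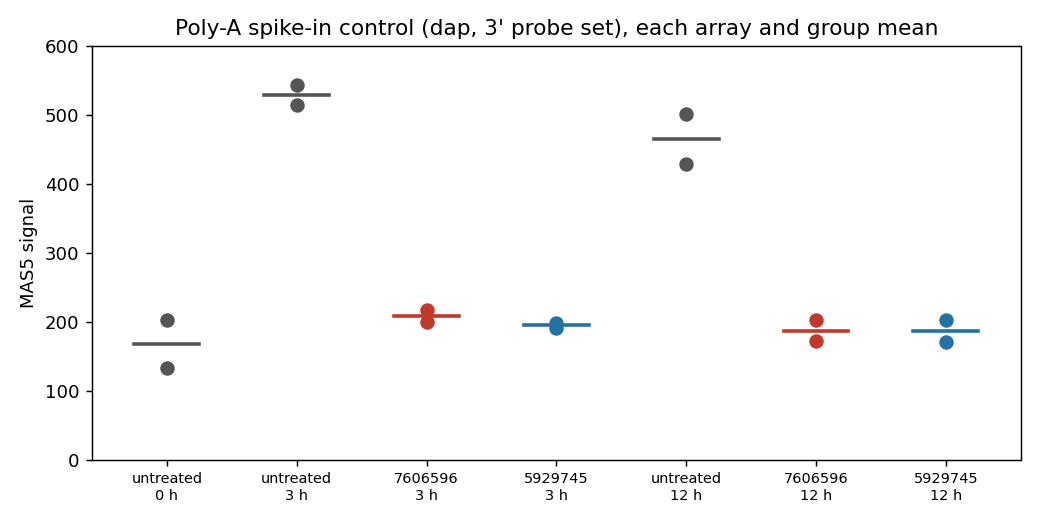
MAS5 signal of the 3' probe set of the poly-A spike-in control dap (y axis) in the 7 groups (x axis), with points for the 2 arrays of each group and a line for their mean. The 4 untreated arrays of 3 h and 12 h lie between 428.6 and 543.5, and the other 10 between 133.2 and 217.2.

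The early effect of 7606596 was read from the 3 h arrays. AT1G19020 had a signal of 2000 ± 52.1 (SD, n = 2) with 7606596 and 285 ± 25.4 in untreated seedlings, a rise of 2.75 ± 0.15 (limma, adjusted p = 1.48e-09). AT3G22620 and AT2G48130, of the lipid-transfer protein family, rose by 2.68 ± 0.20 (adjusted p = 1.36e-07) and 2.64 ± 0.24 (adjusted p = 1.48e-06). AT3G02480, of the late embryogenesis abundant (LEA) family that accumulates in drying seeds, rose by 2.37 ± 0.28 (adjusted p = 3.39e-05), and AT2G36220 by 2.34 ± 0.19 (adjusted p = 5.46e-07). AT1G29090, a cysteine protease, dropped by 3.04 ± 0.18, from 679 ± 164 to 67.6 ± 11.2 (adjusted p = 7.88e-09).

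Further falls at 3 h were those of AT3G13610, an oxygenase of scopoletin synthesis (-1.63 ± 0.25, adjusted p = 0.000549), and AT1G30760, of the berberine bridge enzyme family (-1.53 ± 0.19, adjusted p = 7.15e-05). The glycosyl hydrolase gene AT4G16260 and AT2G17710 changed by -1.49 ± 0.19 (adjusted p = 6.87e-05) and -1.26 ± 0.16 (adjusted p = 7.43e-05). AT3G15670, another LEA gene, rose by 2.40 ± 0.47 (adjusted p = 0.00478), and AT4G22212 fell by 1.27 ± 0.32 (adjusted p = 0.0267). The call of AT3G15670 ended without 7606596 replicate 2 (2.29, adjusted p = 0.0643), without untreated replicate 1 (1.81, adjusted p = 0.0872) and with an offset of 1 (3.07, adjusted p = 0.0774), and with an offset of 64 its rise was 1.54. That of AT4G22212 ended without 7606596 replicate 2 (-0.91, adjusted p = 0.261) or untreated replicate 2 (-0.80, adjusted p = 0.245).

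Of the 20 plastid-encoded photosynthesis genes, 7 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 0.17 and a camera adjusted p of 0.000722. The list had an adjusted p = 0.41 with an estimated correlation. Without 7606596 replicates 1 and 2 the number that rose was 1 and 1, and without untreated replicates 1 and 2 it was 3 and 3. psbC, a photosystem II core protein, rose by 0.83 ± 0.14 (adjusted p = 0.00194) against untreated seedlings of 3 h. Its mean signal of 7348 with 7606596 lay below the 8815 at 0 h. The same held for psbB, psaA and psbD (7591, 11380 and 3706 against 12000, 14760 and 5454). psbB, psaA and psbD rose by 0.56 ± 0.12, 0.52 ± 0.13 and 0.67 ± 0.17. The calls of these 3 ended without 7606596 replicate 1, 7606596 replicate 2 or untreated replicate 1. Their log2 values were then from 0.35 for psaA to 0.70 for psbD, with adjusted p from 0.05 to 0.269. The call of psbD also ended without untreated replicate 2 (0.67, adjusted p = 0.11). In the plastid-encoded housekeeping list 1 of 5 genes rose (2 adjusted over the list alone), and 0 without untreated replicate 2. Of 15 plastid-encoded ribosomal protein genes 1 rose and 3 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.32). Without 7606596 replicates 1 and 2 the numbers were 0 and 2, and 0 and 1, and without untreated replicates 1 and 2 they were 1 and 1, and 0 and 2. Of 10 NDH complex genes 2 rose and 1 fell (3 and 2 adjusted over the list alone; camera adjusted p = 0.808). Without either 7606596 replicate or untreated replicate 2 the numbers were 1 and 0, and without untreated replicate 1 they were 2 and 0.

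All 3 measured genes of the abscisic acid and drought list rose, also adjusted over the list alone, with a median of 1.85 and a camera adjusted p of 4.09e-07 (adjusted p = 0.0698 with an estimated correlation). The dehydrin LTI30 (AT3G50970) rose by 1.85 ± 0.19 (adjusted p = 7.47e-06), LEA4-5 (AT5G06760) by 2.0 ± 0.27 (adjusted p = 0.000122) and the dehydrin COR47 (AT1G20440) by 0.60 ± 0.12 (adjusted p = 0.00723). LEA4-5 is also a LEA gene. In a later list of vegetative abscisic acid genes, limma called 2 of 7 measured members higher and 0 lower, again LTI30 and COR47. The others changed by -0.23 to 0.33, so a general response to abscisic acid was not seen in that list. COR47 lost its call without 7606596 replicate 2 (0.53, adjusted p = 0.093) or untreated replicate 1 (0.56, adjusted p = 0.0712). List members named here for counts under 3, such as the next genes, were chosen after their values were seen. In the xenobiotic detoxification list 2 of 5 genes rose (2 rose and 1 fell adjusted over the list alone), with a camera adjusted p of 0.116. They were the alkenal reductase AER by 1.0 (adjusted p = 9.9e-05) and the glucosyltransferase UGT73B5 by 0.75 (adjusted p = 0.0344). The call of UGT73B5 ended without any 1 of the 4 arrays compared (0.72 to 0.77, adjusted p from 0.119 to 0.152). The small heat shock gene AT2G29500 rose by 1.55 (adjusted p = 0.000507) as 1 of 4 in its list, also adjusted over the list alone (camera adjusted p = 0.0574). The zinc finger gene STZ, the measured member of the reactive oxygen list, rose by 1.15 (adjusted p = 0.00014). The stromal processing peptidase gene SPP, the measured member of plastid protein import, fell by 0.52 (adjusted p = 0.0113). The call of SPP ended without 7606596 replicate 1 (-0.49, adjusted p = 0.0906), 7606596 replicate 2 (-0.55, adjusted p = 0.0629) or untreated replicate 1 (-0.40, adjusted p = 0.133).

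No nuclear list of pigment or photosynthesis genes had a called member at 3 h. Limma called 0 of 9 chlorophyll synthesis genes, 2 of them with an unadjusted p under 0.05, and their changes ran from -0.34 to 0.49. It called 0 of 3 light-harvesting genes (0 with unadjusted p under 0.05), 0 of 3 Calvin cycle genes (0), 0 of 4 nuclear photosystem subunits (2) and 0 of 6 nuclear genes of plastid ribosomal proteins (1). Adjusted over the list alone, 2 photosystem subunits were lower and 0 members of the other 4 lists were called. Most genes of these lists had no kept probe set with a single gene name. These counts, here and in the comparisons below, therefore leave open how the rest of each list changed.

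Limma called 799 of 15922 probe sets at 3 h with 7606596, 492 higher and 307 lower. Of these, 152 were at least 2-fold higher and 32 at least 2-fold lower, and 360 carried a single named gene. The untreated 3 h arrays had the higher poly-A signals, so the effect of the compound and that difference between arrays cannot be told apart here. Against the 0 h arrays, which had the lower poly-A level but also 3 h less in the medium, 211 of the 492 and 41 of the 307 were called in the same direction. Independent calls would share 24.5 and 8.19, and both comparisons use the same treated arrays. The count was 397 and 252 without 7606596 replicates 1 and 2, 372 and 505 without untreated replicates 1 and 2, and 471 with no variance trend.

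After 12 h with 7606596, the LEA gene AT3G02480 had a signal of 388 ± 109 (SD, n = 2) with the compound and 57.1 ± 12.3 without it, a rise of 2.45 ± 0.28 (limma, adjusted p = 9.05e-05). AT3G17520 rose by 2.09 ± 0.31 (adjusted p = 0.00122). AT3G15670 and AT2G23110 rose by 3.37 ± 0.47 (adjusted p = 0.000582) and 2.48 ± 0.29 (adjusted p = 9.05e-05). Their untreated signals of 4.06 ± 1.86 and 24.3 ± 21.5 lay below the filter level of 42.3, so the size of these rises depends on the offset: 5.29 and 3.26 with an offset of 1, and 1.92 and 1.57 with an offset of 64. AT3G53040 rose by 1.81 ± 0.28 (adjusted p = 0.00153), but not without untreated replicate 1 (1.52, adjusted p = 0.0524), and AT2G36220 by 1.61 ± 0.19 (adjusted p = 0.000113). AT4G39200 fell by 1.22 ± 0.18 (adjusted p = 0.00103). ARLA1C fell from 922 ± 173 to 377 ± 74.5, but its call ended without 7606596 replicate 1 (-1.06) or untreated replicate 1 (-1.07). AT1G29090 was still lower, by -0.91 ± 0.18 (adjusted p = 0.0158), but not without 7606596 replicate 1 (-0.81, adjusted p = 0.186), untreated replicate 1 (-0.89, adjusted p = 0.161) or untreated replicate 2 (-0.92, adjusted p = 0.085).

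Plastid-encoded photosynthesis genes were again among those higher at 12 h. In this list 6 of 20 rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.22 and a camera adjusted p of 3.36e-08 (adjusted p = 0.134 with an estimated correlation). The number that rose was 2 without 7606596 replicate 1, and 3 and 3 without untreated replicates 1 and 2. psbB had a signal of 4943 ± 284 (SD, n = 2) with 7606596 and 2195 ± 20.1 without it, a rise of 1.16 ± 0.12 (adjusted p = 2.59e-05). The photosystem II reaction centre gene psbD rose by 1.3 ± 0.17 (adjusted p = 0.000359). For psbC the rise was 0.86 ± 0.14 and for petA, the cytochrome f gene, 0.69 ± 0.12. These rises are against untreated seedlings of 12 h, and with 7606596 the mean signals of these genes lay below those at 0 h. They were 4943, 2615, 5183 and 11770 for psbB, psbD, psbC and petA, against 12000, 5454, 8815 and 15530 at 0 h. The call of psbC ended without 7606596 replicate 1 (0.77, adjusted p = 0.0718) or untreated replicate 1 (0.84, adjusted p = 0.0566). That of petA ended without 7606596 replicate 1 (0.63, adjusted p = 0.0828) or untreated replicate 2 (0.56, adjusted p = 0.0907).

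In the plastid-encoded housekeeping list 2 of 5 genes rose (4 adjusted over the list alone), with a camera adjusted p of 1.19e-05 (adjusted p = 0.134 with an estimated correlation). The RNA polymerase gene rpoB rose by 1.08 ± 0.17 (adjusted p = 0.00169). The acetyl-CoA carboxylase gene accD rose by 0.92 ± 0.17 (adjusted p = 0.00964), but not without 7606596 replicate 1 (0.80, adjusted p = 0.143), untreated replicate 1 (1.01, adjusted p = 0.0533) or untreated replicate 2 (0.82, adjusted p = 0.101). The plastid ribosomal protein gene rps14 rose, but not with the replicate block (limma, 1.19, adjusted p = 0.0586) or an offset of 64 (0.95, adjusted p = 0.0537). Its call also ended without 7606596 replicate 2 (0.67), untreated replicate 1 (1.54) or untreated replicate 2 (0.85). With rps14, 2 of 15 plastid-encoded ribosomal protein genes rose and 1 fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.13). The numbers were 1 and 0 without 7606596 replicate 1 or untreated replicate 1, 1 and 1 without 7606596 replicate 2, and 0 and 2 without untreated replicate 2. Of 10 NDH complex genes 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.056), or 1 without either 7606596 replicate or untreated replicate 1 and 0 without untreated replicate 2. Of the abscisic acid and drought genes 2 of 3 rose (3 adjusted over the list alone), with a camera adjusted p of 3.28e-05 (adjusted p = 0.134 with an estimated correlation). LEA4-5 rose by 1.44 ± 0.27 (adjusted p = 0.00775) and LTI30 by 0.89 ± 0.19 (adjusted p = 0.0247). LTI30 was the 1 called higher of the 7 measured vegetative abscisic acid genes. LEA4-5 lost its call without 7606596 replicate 1 (1.17, adjusted p = 0.174) or untreated replicate 1 (1.31, adjusted p = 0.121). LTI30 lost it without 7606596 replicate 1 (0.61, adjusted p = 0.365), untreated replicate 1 (0.78, adjusted p = 0.297) or untreated replicate 2 (1.0, adjusted p = 0.0682). The nuclear photosystem subunits had a median of -0.25 and a camera adjusted p of 0.0254 (adjusted p = 0.296 with an estimated correlation and 0.0877 without the filter). Limma called 0 of the 4, with 3 of unadjusted p under 0.05 and 1 lower adjusted over the list alone. Chlorophyll synthesis had 0 of 9 genes called by limma (2 with unadjusted p under 0.05, changes from -0.29 to 0.25), 0 of 3 light-harvesting genes (0) and 0 of 3 Calvin cycle genes (0), and 0 in each adjusted over the list alone.

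At 12 h with 7606596 limma called 245 probe sets, 181 higher and 64 lower, of which 54 and 5 changed at least 2-fold and 115 carried a single named gene. The untreated 12 h arrays also had the higher poly-A signals, and the 2 differences cannot be told apart. Against 0 h, 51 of the 181 and 27 of the 64 were called in the same direction and 41 and 13 in the opposite one. Independent calls would share 29.6 and 7.91 in the same direction, and both comparisons use the same treated arrays. The count was 63 without 7606596 replicate 1, 62 and 124 without untreated replicates 1 and 2, 133 without the filter and 76 with no variance trend.

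The early effect of 5929745 was read from the 3 h arrays. The mitochondrial gene ccb382, of cytochrome c maturation, had a signal of 667 ± 52.6 (SD, n = 2) with the compound and 185 ± 78.4 in untreated seedlings at 3 h, a rise of 1.82 ± 0.23 (limma, adjusted p = 0.000351). The plastid genes ycf4, of photosystem I assembly, and ndhJ, of the NDH complex, rose by 1.21 ± 0.12 (adjusted p = 5.24e-05) and 1.19 ± 0.14 (adjusted p = 0.000215). AT1G51850, a leucine-rich repeat receptor kinase, rose by 1.63 ± 0.23 (adjusted p = 0.00143), AT4G01870 by 1.4 ± 0.16 (adjusted p = 0.000215) and AT2G30270 by 1.35 ± 0.15 (adjusted p = 0.000215). AT3G28270 fell by 1.06 ± 0.13 (adjusted p = 0.000315) and AT5G26280 fell by 0.81 ± 0.11 (adjusted p = 0.00105).

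The plastid-encoded photosynthesis list had 4 of 20 genes higher and 0 lower with 5929745 at 3 h (8 and 0 adjusted over the list alone), with a median of 0.18 and a camera adjusted p of 0.00049 (adjusted p = 0.389 with an estimated correlation). psbC rose by 0.86 ± 0.14 (adjusted p = 0.00521), psaA by 0.68 ± 0.13 (adjusted p = 0.0173), psbA by 0.63 ± 0.14 (adjusted p = 0.0278) and psbB by 0.50 ± 0.12 (adjusted p = 0.0442). The mean signals with 5929745 lay below 0 h for psbC, psaA and psbB (7483, 12700 and 7291 against 8815, 14760 and 12000). For psbA the signal lay above 0 h (13500 against 12150). All 4 lost the call without 5929745 replicate 1. Without 5929745 replicate 2 it was lost for psaA, psbA and psbB, without untreated replicate 1 for psbC, psaA and psbB, and without untreated replicate 2 for psbA and psbB. The log2 values were then from 0.46 to 0.82 and the adjusted p from 0.0543 to 0.196. With median scaling psbB also lost it (adjusted p = 0.0585). In the housekeeping list 1 of 5 genes rose (4 adjusted over the list alone), with a camera adjusted p of 0.00196 (adjusted p = 0.389 with an estimated correlation). This was accD, by 1.11 ± 0.17 (adjusted p = 0.00317), but not without 5929745 replicate 1 (0.95, adjusted p = 0.064). The nuclear photosystem subunits had a median of -0.22 and a camera adjusted p of 0.0295 (adjusted p = 0.389 with an estimated correlation, 0.281 with quantile normalization and 0.173 without the filter). Limma called 0 of these 4, with 2 of unadjusted p under 0.05 and 1 lower adjusted over the list alone. The abscisic acid and drought genes had a camera adjusted p of 0.0148 (adjusted p = 0.389 with an estimated correlation and 0.25 without the filter) and a median of 0.48. Here limma called 0 of 3, with 2 of unadjusted p under 0.05 and 2 higher adjusted over the list alone. For chlorophyll synthesis limma called 0 of 9 genes (1 with unadjusted p under 0.05, changes from -0.26 to 0.52), 0 of 3 light-harvesting genes (0) and 0 of 3 Calvin cycle genes (0), and 0 in each adjusted over the list alone.

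Limma called 183 probe sets with 5929745 at 3 h, 123 higher and 60 lower, of which 24 and 4 changed at least 2-fold and 96 carried a single named gene. The untreated arrays are those of higher poly-A signal, so the same limit holds as for 7606596. Against 0 h, 43 of the 123 and 17 of the 60 were called in the same direction, where independent calls would share 6.82 and 2.48. Both comparisons use the same treated arrays. The count was 61 and 41 without 5929745 replicates 1 and 2, 81 without untreated replicate 1, 75 without the filter and 28 with no variance trend.

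The later effect of 5929745 was read at 12 h. AT1G29090, the cysteine protease that was lower with 7606596, had a signal of 974 ± 59.2 (SD, n = 2) against 380 ± 6.14, a rise of 1.32 ± 0.18 (limma, adjusted p = 0.00107). AT5G11420, a cell wall protein of the DUF642 family, rose by 0.98 ± 0.13 (adjusted p = 0.000866). The expansin-like gene EXLB1 rose by 1.25 ± 0.22 (adjusted p = 0.00673), but not without untreated replicate 1 (1.05, adjusted p = 0.123). AT5G26280 fell by 1.06 ± 0.11 (adjusted p = 0.000278), AT3G44970, a cytochrome P450, fell by 1.05 ± 0.14 (adjusted p = 0.00106) and the plastid gene petL, of the cytochrome b6f complex, fell by 1.0 ± 0.15 (adjusted p = 0.00169).

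With 5929745 at 12 h, 3 of 20 genes of the plastid-encoded photosynthesis list rose and 0 fell (5 rose and 2 fell adjusted over the list alone), with a median of 0.15 and a camera adjusted p of 0.0177 (adjusted p = 0.864 with an estimated correlation, 0.062 with quantile normalization and 0.0829 with the filter at the 60th percentile). psbB rose by 0.85 ± 0.12 (adjusted p = 0.00101) against untreated seedlings of 12 h. Its mean signal of 3976 with 5929745 lay below the 12000 at 0 h, as did those of petA and petD (10640 and 290 against 15530 and 430). petD and petA rose by 0.89 ± 0.19 (adjusted p = 0.0297) and 0.54 ± 0.12 (adjusted p = 0.0334). Both lost the call without 5929745 replicate 2 or either untreated replicate, and petD also without 5929745 replicate 1. The adjusted p was then from 0.0567 to 0.262, with log2 values from 0.40 for petA to 1.04 for petD. In the housekeeping list 1 of 5 genes rose (3 adjusted over the list alone), with a camera adjusted p of 0.0408 (adjusted p = 0.864 with an estimated correlation, and 0.062 and 0.0829 with these 2 settings). It was rpoB, by 0.88 ± 0.17 (adjusted p = 0.0121), but not without 5929745 replicate 2 (0.85, adjusted p = 0.0756), untreated replicate 1 (0.92, adjusted p = 0.104) or untreated replicate 2 (0.85, adjusted p = 0.0927). The plastid ribosomal protein gene rps14 rose by 1.58 ± 0.29 (adjusted p = 0.00958), but not without 5929745 replicate 2 (1.33, adjusted p = 0.109) or untreated replicate 2 (1.23, adjusted p = 0.117). The list of 15 plastid-encoded ribosomal proteins was drawn from the annotation before any fold change was seen. Of these 1 rose and 7 fell (2 rose and 10 fell adjusted over the list alone), with a camera adjusted p of 4.79e-06 (adjusted p = 0.177 with an estimated correlation). The number that fell was 4 without 5929745 replicate 1, and 1 and 3 without untreated replicates 1 and 2. The gene that rose was not called without 5929745 replicate 2 or untreated replicate 2. Among them rps18 fell by 0.92 ± 0.14 (adjusted p = 0.00256). Among chlorophyll synthesis genes limma called 0 of 9 (2 with unadjusted p under 0.05, changes from -0.28 to 0.27), 0 of 3 light-harvesting genes (0), 0 of 3 Calvin cycle genes (0), 0 of 4 photosystem subunits (0) and 0 of 3 abscisic acid and drought genes (1). Adjusted over the list alone, 1 drought gene was higher and 0 members of the other lists were called.

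**Figure D2:**
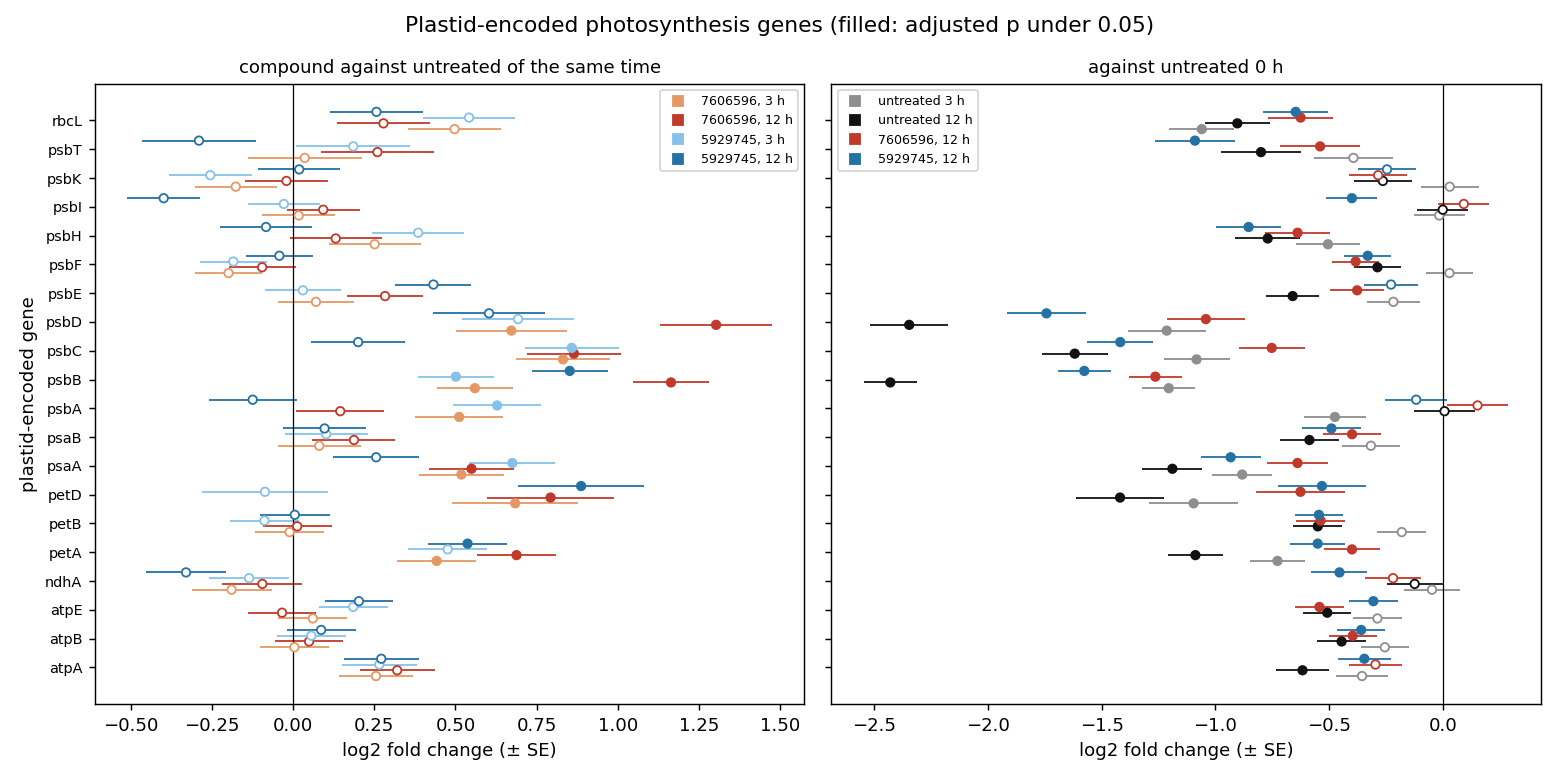
Log2 fold change with its standard error (x axis) of the 20 plastid-encoded photosynthesis genes (y axis), for each compound against untreated seedlings of the same time (left) and for the untreated groups and the 12 h compound groups against 0 h (right), with filled points at adjusted p under 0.05 and 2 arrays per group. The genes psbB and psbD lie highest on the left, at 1.16 and 1.3 with 7606596 at 12 h, and lowest on the right in untreated seedlings at 12 h, at -2.43 and -2.35. With 7606596 at 12 h their mean signals were also below those at 0 h (4943 against 12000, and 2615 against 5454).

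With 5929745 at 12 h limma called 223 probe sets, 132 higher and 91 lower, of which 19 and 11 changed at least 2-fold and 118 carried a single named gene. The poly-A levels of treated and untreated arrays differed here too and cannot be told apart from the compound. Against 0 h, 28 of the 132 and 35 of the 91 were called in the same direction and 31 and 10 in the opposite one. Independent calls would share 22.5 and 11.3 in the same direction, and both comparisons use the same treated arrays. The count was 109 without 5929745 replicate 2, 39 and 72 without untreated replicates 1 and 2, 107 without the filter, 42 with no variance trend and 66 when only the 2 groups were fitted.

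The 2 compounds were then compared directly at the same dose and time, on arrays of the same poly-A level. At 3 h 3 LEA genes and 2 of the lipid-transfer protein family were among those higher with 7606596. AT3G17520 had a signal of 348 ± 19.7 (SD, n = 2) with 7606596 and 48.6 ± 13.3 with 5929745, a difference of 2.51 ± 0.31 (limma, adjusted p = 0.000134). AT3G02480 differed by 2.48 ± 0.28 (adjusted p = 4.47e-05) and AT2G23110 by 1.86 ± 0.29 (adjusted p = 0.00135). AT3G22620 and AT2G48130 differed by 2.79 ± 0.20 (adjusted p = 2.3e-07) and 2.54 ± 0.24 (adjusted p = 5.55e-06). AT1G29090 was lower with 7606596, by -2.91 ± 0.18 (adjusted p = 6.68e-08).

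AT3G15670 was higher with 7606596 at 3 h by 2.88 ± 0.47 (adjusted p = 0.00195), but not without 7606596 replicate 2 (2.77, adjusted p = 0.0514) or with an offset of 1 (3.83, adjusted p = 0.0856), and by 1.77 with an offset of 64. AT1G30760 (-1.56 ± 0.19), AT4G16260 (-1.22 ± 0.19) and the asparaginase gene ASPGB1 (-1.11 ± 0.15) were lower with 7606596, with adjusted p of 0.00013, 0.00131 and 0.000246. AT3G13610 was lower by -1.61 ± 0.25 (adjusted p = 0.00132), but not without 7606596 replicate 2 (-1.39, adjusted p = 0.0514). In the abscisic acid and drought list 2 of 3 genes were higher with 7606596 (3 adjusted over the list alone), with a camera adjusted p of 5.35e-07 (adjusted p = 0.0503 with an estimated correlation). LTI30 was higher by 1.14 ± 0.19 (adjusted p = 0.00322) and LEA4-5 by 1.52 ± 0.27 (adjusted p = 0.00438). LTI30 lost its call without 5929745 replicate 2 (1.03, adjusted p = 0.0868). LEA4-5 lost it without 5929745 replicate 2 (1.35, adjusted p = 0.101) or 7606596 replicate 1 (1.43, adjusted p = 0.0757).

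The heat shock list was higher with 7606596 than with 5929745 at 3 h as a set, with a camera adjusted p of 8.33e-07 (adjusted p = 0.0503 with an estimated correlation) and a median of 0.85. Limma called 0 of its 4 genes, all 4 had an unadjusted p under 0.05, 4 were higher adjusted over the list alone, and their differences ran from 0.70 to 0.98. The xenobiotic detoxification list had a camera adjusted p of 0.0252 (adjusted p = 0.108 with an estimated correlation) and a median of 0.31. Limma called 0 of its 5 genes, with 2 of unadjusted p under 0.05 and 2 higher adjusted over the list alone. Of the plastid-encoded photosynthesis genes at 3 h limma called 0 of 20 over all kept probe sets, with 1 of unadjusted p under 0.05, 1 higher adjusted over the list alone and differences from -0.16 to 0.77. For chlorophyll synthesis limma called 0 of 9 genes, with 1 of unadjusted p under 0.05, 0 adjusted over the list alone and differences from -0.36 to 0.25.

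LEA genes still differed between the compounds at 12 h. AT3G02480 had a signal of 388 ± 109 (SD, n = 2) with 7606596 and 49.5 ± 31.5 with 5929745, a difference of 2.69 ± 0.28 (limma, adjusted p = 3.14e-05), and AT3G17520 differed by 2.52 ± 0.31 (adjusted p = 0.000247). AT1G29090 was lower with 7606596 by -2.23 ± 0.18 (adjusted p = 1.66e-06), AT5G62280 by -1.33 ± 0.13 (adjusted p = 1.19e-05) and AT2G17710 by -1.11 ± 0.16 (adjusted p = 0.00132). The expansin gene EXPA8, a member of the added list of wall-loosening proteins, was lower by -1.36 ± 0.18 (adjusted p = 0.000511).

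AT3G15670, AT3G53040, LEA18 and AT2G23110 were also higher with 7606596 at 12 h, by 2.74 ± 0.47, 1.89 ± 0.28, 1.69 ± 0.35 and 1.68 ± 0.29. The signal of AT3G15670 with 5929745, at 21.0, lay below the filter level of 42.3, and its difference was 4.41 with an offset of 1 and 1.64 with an offset of 64. All 4 lost the call without 7606596 replicate 1 (2.27, 1.71, 1.43 and 1.45, with adjusted p of 0.171, 0.0589, 0.355 and 0.166). All but AT3G53040 also lost it without 5929745 replicate 1 (1.86, 0.82 and 1.57, with adjusted p of 0.0783, 0.191 and 0.0569). The homeodomain gene HAT2 was lower by -1.13 ± 0.19 (adjusted p = 0.00573), but not without 7606596 replicate 1 (-1.01, adjusted p = 0.133). LEA4-5, the called 1 of 3 abscisic acid and drought genes (2 adjusted over the list alone), was higher by 1.64 ± 0.27 (adjusted p = 0.00389). This call ended without 7606596 replicate 1 (1.38, adjusted p = 0.134) or 5929745 replicate 1 (1.41, adjusted p = 0.0546). The camera adjusted p of the list was 0.0103 (adjusted p = 0.371 with an estimated correlation and 0.151 without the filter).

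The plastid-encoded photosynthesis list was higher with 7606596 than with 5929745 at 12 h, with 2 of 20 genes called higher and 0 lower (4 and 0 adjusted over the list alone). It had a median of 0.12 and a camera adjusted p of 0.00251 (adjusted p = 0.371 with an estimated correlation). psbC was higher by 0.66 ± 0.14 (adjusted p = 0.0332) and psbI by 0.49 ± 0.11 (adjusted p = 0.0423). The call of psbC ended without 7606596 replicate 1 (0.57, adjusted p = 0.416) or 5929745 replicate 2 (0.46, adjusted p = 0.299). That of psbI ended without 7606596 replicate 1 (0.39, adjusted p = 0.59), 5929745 replicate 2 (0.40, adjusted p = 0.252) or 5929745 replicate 1 (0.58, adjusted p = 0.0564), or with median scaling (adjusted p = 0.0632). The housekeeping list had a camera adjusted p of 0.0274 (adjusted p = 0.371 with an estimated correlation and 0.0755 without the filter), and limma called 0 of its 5 genes, with 2 of unadjusted p under 0.05 and 1 higher adjusted over the list alone. Of the 9 chlorophyll synthesis genes limma called 0, with 2 of unadjusted p under 0.05, 0 adjusted over the list alone and differences from -0.26 to 0.23.

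**Figure D3:**
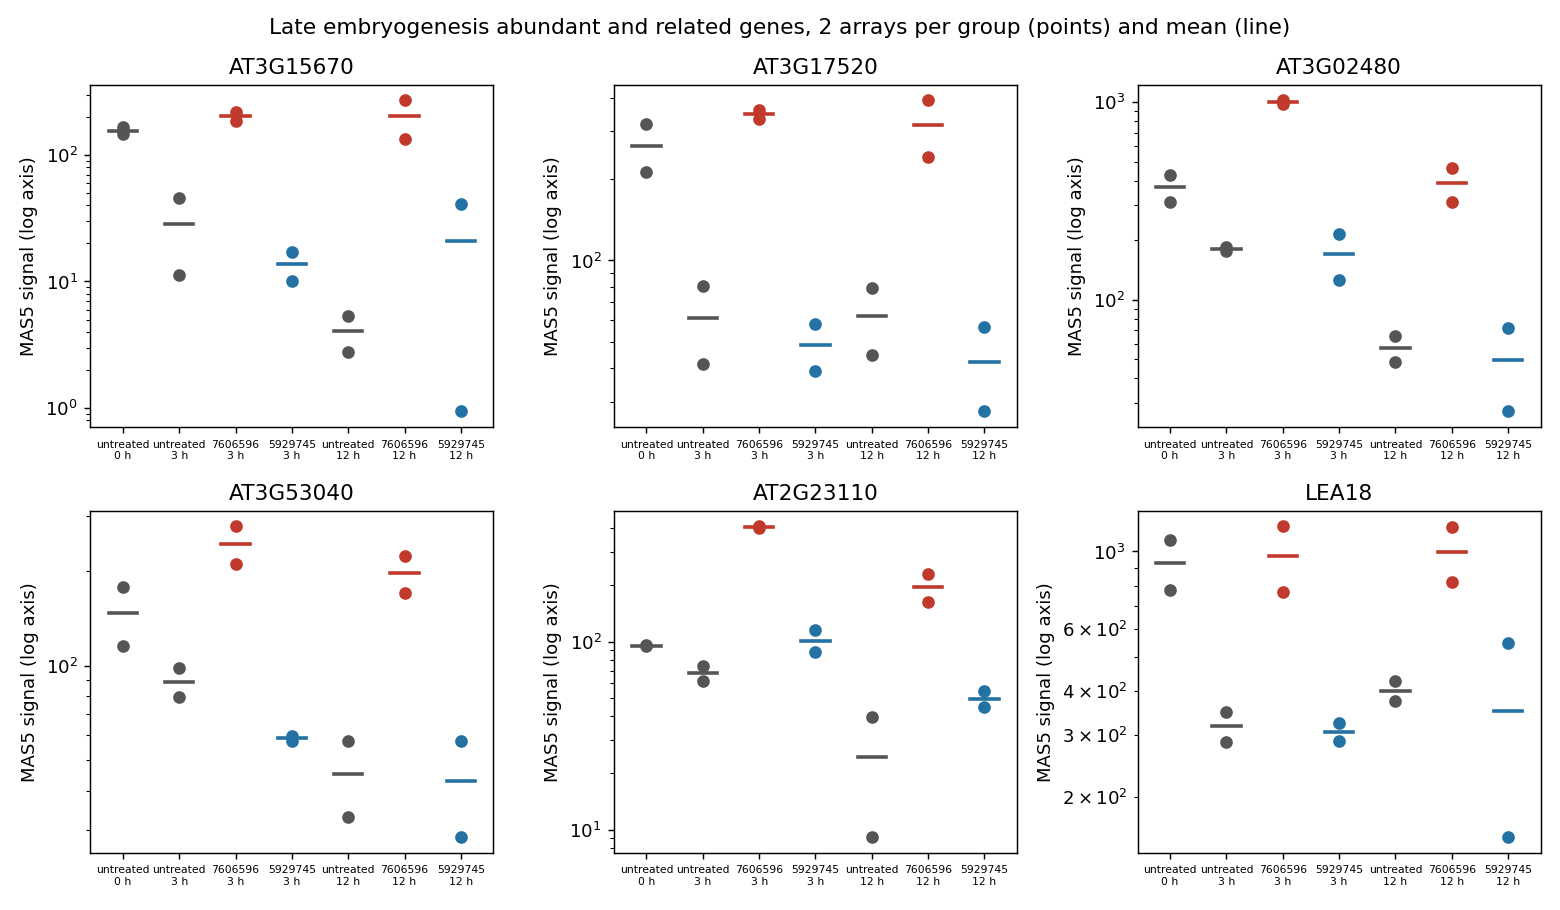
MAS5 signal on a log axis (y) of 6 late embryogenesis abundant and related genes in the 7 groups (x), with points for the 2 arrays and a line for their mean. In each panel the means of the 7606596 groups lie above those of the 5929745 and untreated groups of the same time, as for AT3G17520 with 348 against 48.6 and 61.0 at 3 h.

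In the direct comparison limma called 146 probe sets at 3 h, 117 higher and 29 lower with 7606596, and 135 at 12 h, 80 higher and 55 lower. At both times 47 were higher and 8 lower, where independent calls would share 0.588 and 0.1. Of the probe sets higher with 7606596 than in untreated seedlings, 98 of 492 at 3 h and 42 of 181 at 12 h were also higher than with 5929745. Of the lower ones, 20 of 307 and 14 of 64 were also lower than with 5929745. Both comparisons use the same 7606596 arrays, which by itself adds to this overlap, and no value without change was simulated for it. The 3 h count was 92 and 65 without 7606596 replicates 1 and 2, 80 and 76 without 5929745 replicates 1 and 2, 91 without the filter, 86 with the filter at the 60th percentile, 92 with no variance trend and 237 when only the 2 groups were fitted. The 12 h count was 28 without 7606596 replicate 1, 76 without 5929745 replicate 1, 65 without the filter, 46 with no variance trend and 32 when only the 2 groups were fitted.

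The further calls given here come from lists with few measured members. MCCA, the measured gene of dark and sugar starvation, rose at 12 h by 0.65 (limma, adjusted p = 0.00596) with 7606596 and 0.59 (adjusted p = 0.0157) with 5929745. WES1 (AT4G27260), which conjugates auxin, rose as 1 of 4 early auxin genes by 0.58 (adjusted p = 0.0163) and 0.67 (adjusted p = 0.00752). All 4 calls ended without untreated 12 h replicate 1 or 2 (0.54 to 0.71, adjusted p from 0.0555 to 0.128). That of WES1 with 7606596 also ended without 7606596 replicate 1 (0.47, adjusted p = 0.247), and those with 5929745 without 5929745 replicate 2 (WES1 0.59, adjusted p = 0.0641, and MCCA 0.43, adjusted p = 0.15). With 5929745 at 3 h STZ rose by 0.74 (adjusted p = 0.0257) and AER by 0.64 (adjusted p = 0.0219). Both calls ended without 5929745 replicate 2 (0.71, adjusted p = 0.203, and 0.47, adjusted p = 0.271) or untreated replicate 2 (0.61, adjusted p = 0.142, and 0.57, adjusted p = 0.115). That of STZ also ended without 5929745 replicate 1 (0.76, adjusted p = 0.105) and that of AER without untreated replicate 1 (0.71, adjusted p = 0.06). AER was higher with 7606596 than with 5929745 at 12 h by 0.59 (adjusted p = 0.0392), but not without 7606596 replicate 1 (0.61, adjusted p = 0.249), 7606596 replicate 2 (0.56, adjusted p = 0.138) or 5929745 replicate 1 (0.44, adjusted p = 0.266). This call also ended with median scaling (0.59, adjusted p = 0.056), without the filter (adjusted p = 0.0856) and with no variance trend (adjusted p = 0.167), and that of AER with 5929745 at 3 h with no variance trend (adjusted p = 0.101).

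In the 6 comparisons of a compound with untreated seedlings or with the other compound, limma called 0 genes of 7 further lists. Its numbers of genes with an unadjusted p under 0.05 were at most 1 of 3 cell cycle genes, 0 of 2 carotenoid and MEP pathway genes, 1 of 2 root tissue markers and 2 of 2 hypoxia genes. For the single measured genes they were 0 for defence and salicylate (WRKY53), 0 for plastid transcription machinery (AT5G15700) and 1 for the circadian clock (GI). No gene of the greening regulators, jasmonate, or flavonoid and anthocyanin lists had a kept probe set with a single gene name, so these lists were not tested.

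The overlap of the 2 compounds asks which genes moved with both. AT2G36220, higher with 7606596 at 3 h, had a signal of 3151 ± 503 (SD, n = 2) with it and 1338 ± 188 with 5929745, against 606 ± 19.2 in untreated seedlings. The signals of psbC were 7348 ± 756 and 7483 ± 720 against 4112 ± 137, and those of ycf4 11000 ± 1060 and 11050 ± 160 against 4756 ± 94.8. At 3 h limma called 92 probe sets higher and 34 lower with both compounds, where independent calls would share 3.8 and 1.16. At 12 h it called 50 higher and 19 lower with both, where independent calls would share 1.5 and 0.366, and 2 in opposite directions. Both comparisons use the same untreated arrays. In simulations of unchanged groups that shared them, the mean number of common calls was 0.06 at 3 h and 0.04 at 12 h, against 126 and 69 found. With no change simulated, common calls were almost absent by design. These numbers do not show how many the shared arrays add where each compound has changes of its own. Across probe sets, which are not independent replicates, the fold changes of the compounds correlated with r = 0.656 at 3 h and 0.604 at 12 h. Sharing the untreated arrays alone gave 0.5 and 0.501 in the simulations. The covariances were 0.0644 and 0.0479 against 0.02 at both times.

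These shared calls carry the poly-A difference in full, as both compounds lay at the lower level and the untreated arrays at the higher one. The 126 shared calls of 3 h had a median change of 0.77 against the untreated 3 h arrays and of 0.23 against the 0 h arrays, in the direction of the call. The number was 77 and 68 without 7606596 replicates 1 and 2, 42 and 34 without 5929745 replicates 1 and 2, 58 without untreated replicate 1 and 53 without the filter. At 12 h it was 29 without 7606596 replicate 1, 35 without 5929745 replicate 2, 16 and 34 without untreated replicates 1 and 2 and 37 without the filter.

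The interaction tested whether the effect of a compound differed between 12 h and 3 h, and a constant difference between array levels cancels in it. A difference that changes with time does not cancel. The mean log2 hybridization signals were 10.82 and 10.79 on the untreated 3 h arrays, and 10.17 and 10.23 on those of 12 h. The effect of 7606596 on AT3G22620 was smaller at 12 h by -2.28 ± 0.28 (limma, adjusted p = 0.0014), as the signal with the compound went from 2324 ± 456 (SD, n = 2) at 3 h to 197 ± 2.32 at 12 h. AT2G48130 had a difference of -2.35 ± 0.34 (adjusted p = 0.0044) and AT1G19020 of -1.46 ± 0.21 (adjusted p = 0.0044). The fall of AT1G29090 was weaker at 12 h by 2.14 ± 0.26 (adjusted p = 0.0014). For 5929745 the difference of the effects was -1.51 ± 0.20 for ndhJ and 1.4 ± 0.18 for AT5G11420 (adjusted p = 0.00343 for both). The mean signals of ndhJ with and without the compound were 3472 and 1512 at 3 h, and 2135 and 2682 at 12 h. Those of AT5G11420 were 2684 and 3577 at 3 h, and 2474 and 1243 at 12 h, so for both genes the difference of the means changed sign. The interaction tests the difference between the effects, not the direction at each time. With no variance trend the adjusted p of these 6 genes were from 0.0833 to 0.132, and without the filter that of AT2G48130 was 0.0559.

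Limma called 21 probe sets in the interaction for 7606596, 13 positive and 8 negative, and 18 for 5929745, 6 positive and 12 negative. The first count was 7 without 7606596 3 h replicate 2, without untreated 12 h replicate 1 or without the filter, 35 with an offset of 64 and 0 with no variance trend. The second was 11 and 2 without 5929745 3 h replicates 1 and 2, 75 and 7 without 5929745 12 h replicates 1 and 2, 4 and 3 without untreated 12 h replicates 1 and 2, 3 without the filter and 0 with no variance trend. Of the probe sets called against untreated seedlings with 7606596, 96 were higher and 21 lower at both times, and with 5929745 12 and 9. In the interactions, camera gave no fixed list an adjusted p under 0.05; the lowest were 0.058 for abscisic acid and drought with 7606596 and 0.758 for heat shock with 5929745.

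Untreated seedlings at 3 h and 12 h were compared with 0 h to give the background of time in the medium and time of day. AT4G34950 had a signal of 87.4 ± 9.42 (SD, n = 2) at 0 h, 556 ± 64.7 at 3 h and 3258 ± 393 at 12 h, with rises of 2.46 ± 0.16 and 4.98 ± 0.16 (limma, adjusted p = 1.86e-08 and 3.6e-14). The LEA gene AT3G17520 fell by 1.89 ± 0.31 at 3 h (adjusted p = 0.000708), from 266 ± 76.1 to 61.0 ± 27.5. AT3G13610 rose by 2.40 ± 0.25 at 3 h (adjusted p = 5.3e-06). At 12 h AT1G55960 fell by 3.66 ± 0.12 (adjusted p = 3.6e-14) and AT4G33980 rose by 3.86 ± 0.20 (adjusted p = 3.81e-11).

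Many photosynthesis genes, though not all, had lower signals at 3 h and 12 h than at 0 h. The mean signal of the plastid gene petL, not in the list tested, rose from 3533 at 0 h to 5309 at 3 h and 6703 at 12 h. The untreated 3 h and 12 h arrays also had lower 25S rRNA signals (220 against 489 on the other 10). Time and this difference between arrays cannot be told apart in comparisons with 0 h. Of the plastid-encoded photosynthesis list 9 of 20 fell at 3 h and 16 at 12 h, and 0 rose (13 and 16 fell and 0 rose adjusted over the list alone). The medians were -0.38 and -0.64, with camera adjusted p of 1.67e-10 and 1.03e-10 (adjusted p = 0.163 and 0.0797 with an estimated correlation). psbB fell by 1.21 ± 0.12 at 3 h and fell by 2.43 ± 0.12 at 12 h (adjusted p = 2.21e-06 and 1.55e-11). In the plastid-encoded housekeeping list 3 of 5 genes fell at 3 h and 4 at 12 h (4 at both times adjusted over the list alone). Its camera adjusted p were 7.09e-05 and 0.00106 (adjusted p = 0.163 and 0.151 with an estimated correlation). Among them accD changed by -1.28 ± 0.17 and -1.25 ± 0.17. In the Calvin cycle list 1 of 3 genes fell at 3 h and 3 at 12 h (2 and 3 adjusted over the list alone). Its camera adjusted p were 0.021 and 0.00142 (adjusted p = 0.163 and 0.0797 with an estimated correlation, and 0.239 and 0.0853 with quantile normalization).

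Nuclear light-harvesting and photosystem genes fell at 12 h. All 4 photosystem subunits were lower (4 adjusted over the list alone), with a camera adjusted p of 0.000104 (adjusted p = 0.0797 with an estimated correlation). PSBY fell by 1.08 ± 0.10 (adjusted p = 1.23e-07). PSAE-1 (-0.58 ± 0.12) lost its call with quantile normalization (-0.12, adjusted p = 0.414). Of 3 light-harvesting genes 2 fell (2 adjusted over the list alone), with a camera adjusted p of 0.00424 (adjusted p = 0.0797 with an estimated correlation and 0.0528 with quantile normalization). They were LHCB4.2, by -2.16 ± 0.11 (adjusted p = 3.1e-11), and LHCB4.1, by -0.67 ± 0.10 (adjusted p = 2.86e-05), the latter not with quantile normalization (-0.16, adjusted p = 0.144). Of 6 plastid ribosomal protein genes 3 fell (3 adjusted over the list alone; camera adjusted p = 0.0124, adjusted p = 0.151 with an estimated correlation and 0.201 with quantile normalization). The number was 1 without untreated 12 h replicate 2. AT2G43030 (-0.32) lost its call there (-0.24, adjusted p = 0.193), with quantile normalization (-0.03, adjusted p = 0.833), and without 0 h replicate 1 (-0.35, adjusted p = 0.0586) or 2 (-0.30, adjusted p = 0.109). Of 9 chlorophyll synthesis genes 2 rose and 3 fell (2 and 3 adjusted over the list alone), with a camera adjusted p of 0.126. PORB, a protochlorophyllide oxidoreductase and the called 1 of 9 at 3 h, rose by 1.26 ± 0.12 at 3 h and 1.11 ± 0.12 at 12 h (adjusted p = 2.16e-06 and 1.15e-06) and CHLM, of magnesium protoporphyrin methylation, fell by 0.87 ± 0.12 (adjusted p = 1.88e-05). In the cell cycle list 1 of 3 genes rose and 2 fell (1 and 2 adjusted over the list alone; camera adjusted p = 0.279). PRL, which rose, lost its call with quantile normalization (0.48, adjusted p = 0.0586), with median scaling (0.48, adjusted p = 0.0541), without the filter (0.58, adjusted p = 0.0527), without 0 h replicate 1 (0.49, adjusted p = 0.135) or without untreated 12 h replicate 1 (0.48, adjusted p = 0.156). AUR2, which fell, lost it without 0 h replicate 2 (-0.62, adjusted p = 0.0853) or untreated 12 h replicate 1 (-0.71, adjusted p = 0.0538).

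At 3 h the abscisic acid and drought list had 2 of 3 genes lower (2 adjusted over the list alone; camera adjusted p = 0.036, adjusted p = 0.309 with an estimated correlation, 0.0713 with quantile normalization and 0.227 without the filter), with LEA4-5 lower by -1.81 ± 0.27 (adjusted p = 0.000229). The other, LTI30, was not called without 0 h replicate 2 (-0.54, adjusted p = 0.153) or untreated 3 h replicate 2 (-0.74, adjusted p = 0.0742), or with no variance trend (-0.82, adjusted p = 0.05). The heat shock list had 1 of 4 higher (2 adjusted over the list alone; camera adjusted p = 0.021, adjusted p = 0.302 with an estimated correlation and 0.175 without the filter), which was AT5G48570, by 1.53 ± 0.21 (adjusted p = 0.000143). Of the clock genes GI was measured, and it rose by 1.72 at 3 h and was not called at 12 h (0.26).

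Limma called 1921 probe sets in untreated seedlings at 3 h against 0 h, 1061 higher and 860 lower, and 5586 at 12 h, 3161 higher and 2425 lower. With median scaling the balance turned, to 40.6% higher at 3 h in place of 55.2% and to 43.7% at 12 h in place of 56.6%. Both comparisons cross the poly-A levels. The untreated 12 h and 3 h arrays both lie at the higher poly-A level but differ in their hybridization controls (10.17 and 10.23 against 10.82 and 10.79 in mean log2 signal). Between them 5449 probe sets differed, 2898 higher and 2551 lower at 12 h. There all 4 photosystem subunits, 2 of 3 light-harvesting genes and 7 of 20 plastid-encoded photosynthesis genes fell, and 1 of the latter rose (the same numbers adjusted over the lists alone). The camera adjusted p of these lists were 0.000199, 0.0151 and 0.00223 (adjusted p = 0.18, 0.18 and 0.272 with an estimated correlation). The 3 h count was 890 and 1070 without the 0 h replicates 1 and 2, and 1036 and 1172 without the untreated 3 h replicates 1 and 2.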

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

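The tests of time, a difference between the effects of a compound at 12 h and at 3 h, were chosen before the data were examined, and the comparisons with the 0 h arrays and the tests of the genes shared by both compounds after the poly-A signals had been seen.

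A difference between the 2 time points drew attention to 21 probe sets for 7606596 and 18 for 5929745 (limma, adjusted p under 0.05). Of the genes named before for other comparisons, the effect of 7606596 was more positive at 12 h for AT1G29090 (2.14), AT4G16260 (1.62) and the asparaginase gene ASPGB1 (1.06). It was more negative for AT3G22620 (-2.28), AT2G48130 (-2.35), AT1G19020 (-1.46) and AT2G30270 (-1.28). The effect of 5929745 was more positive for EXPA8 (1.49), AT1G29090 (1.45), AT5G11420 (1.4) and AT5G62280 (1.07), and more negative for ndhJ (-1.51), AT2G30270 (-1.48), AT2G44820 (-1.29) and AT4G34950 (-1.28). The effects for 7606596 on AT3G22620, AT1G29090, AT1G19020 and AT2G48130, and for 5929745 on ndhJ and AT5G11420, passed the threshold without each single array. The others lost it without single arrays. With 7606596 this held for AT4G16260 without 7606596 3 h replicate 2, 7606596 12 h replicate 2, untreated 3 h replicate 1 or either untreated 12 h replicate (adjusted p from 0.0545 to 0.0984). It held for AT2G30270 without 7606596 3 h replicate 1, 7606596 12 h replicate 1, untreated 3 h replicate 2 or untreated 12 h replicate 1 (0.0692 to 0.0873), and for ASPGB1 without any of the 8 arrays but untreated 12 h replicate 1 (0.061 to 0.195). With 5929745, AT2G30270 lost it without 5929745 3 h replicate 2 (adjusted p = 0.0677) or untreated 12 h replicate 1 (0.057). AT5G62280 lost it without either 5929745 3 h replicate, untreated 3 h replicate 2 or either untreated 12 h replicate (0.062 to 0.168). AT1G29090 lost it without 5929745 3 h or 12 h replicate 2, untreated 3 h replicate 2 or either untreated 12 h replicate (0.0772 to 0.199), and AT4G34950 and EXPA8 without these or 5929745 3 h replicate 1 (0.0706 to 0.179 and 0.0653 to 0.185). AT2G44820 lost it without any of the 8 arrays but 5929745 12 h replicate 1 (0.0565 to 0.243). With the replicate block, ASPGB1 for 7606596 (adjusted p = 0.0616) and AT1G29090 (0.0507) and AT2G44820 (0.0512) for 5929745 lost it too. So did ASPGB1 (0.0578) and AT2G44820 (0.0554) with an offset of 1 and ASPGB1 with quantile normalization (0.0589). Without the filter the counts for 7606596 and 5929745 were 7 and 3. With no variance trend they were 0 and 0, so none of these calls held there. No explanation was tested for these differences.

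Poly-A spike-in probe sets, which no comparison of the study's groups uses, were higher by a mean log2 difference of 1.21 on the 4 untreated arrays of 3 h and 12 h than on the other 10. Among the biological comparisons, 126 probe sets were called in the same direction with both compounds at 3 h, each against the same untreated arrays. Against those arrays their median change was 0.77, and against the 0 h arrays 0.23 in the direction of the call, with 34 called there in the same direction for both compounds. For 72 of the 126, untreated seedlings at 3 h were called in the opposite direction against 0 h. Separate labelling of the arrays stays open. The change of 0.234 in place of 0.774 does not decide it: these probe sets were chosen for their difference from the untreated 3 h arrays, which by itself makes their change against other arrays smaller and opposite calls more frequent, and the 0 h arrays also differ by 3 h of time. A response shared by both compounds also stays open. Of the 126, 75.4% had the same direction at 12 h with both compounds. With no change at 12 h the use of the same untreated arrays for both gave a mean of 33.4% in 100 simulations (23 to 45.2%). The untreated 12 h arrays have the higher poly-A signals too, so labelling could also have raised this share. For these 126 probe sets the 2 cannot be told apart, since no untreated 3 h array has the lower poly-A level.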

How the results depend on the processing

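Of the alternatives, 2 were added after the poly-A signals had been seen: the 0 h arrays as the reference for the compounds, and the untreated 3 h arrays as that for untreated seedlings at 12 h (5449 calls). Named genes were tested with quantile normalization, median scaling, offsets of 1 and 64, the replicate block and single arrays left out, and none changed its direction, but with the 0 h arrays as the reference 41 of 181 higher and 13 of 64 lower calls of 7606596 at 12 h, and 31 of 132 and 10 of 91 of 5929745, were called in the opposite direction. Of the 2178 values of named genes under those 6 kinds of change, 271 lost the call. The filters, the variance trend and the groups in the fit are not in that count. All 49 list calls of the planned comparisons were lost with an estimated correlation, 11 with quantile normalization, 13 without the filter, 2 with an offset of 1 and 10 of the 38 that could be tested with the filter at the 60th percentile. With median scaling, an offset of 64 or the replicate block 0 of these list calls were lost. In the untreated seedlings the share of higher calls fell with median scaling from 55.2% to 40.6% at 3 h and from 56.6% to 43.7% at 12 h, where that scaling shifted the median of all probe sets by -0.0976. For the other changes the cause was not tested. A lone array in a group is assumed to vary like the other groups. MAS5 signals near the background limit what low transcripts show: the filter left 15922 of 22810 probe sets, and the call of AT3G15670 with 7606596 at 3 h, at a signal of 28.7 in untreated seedlings, ended with an offset of 1 (adjusted p = 0.0774).

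Without the filter, which tests more probe sets, the counts were 133 for 7606596 at 12 h, 75 and 107 for 5929745 at 3 h and 12 h, 91 and 65 between the compounds, 7 and 3 for the time effects of 7606596 and 5929745, and 53 and 37 for the calls shared by both at 3 h and 12 h. With the filter at the 60th percentile the count between the compounds at 3 h was 86. With no variance trend the counts were 471 and 76 for 7606596, 28 and 42 for 5929745, 92 and 46 between the compounds, and 0 and 0 for the time effects. An offset of 64 gave 35 for the time effect of 7606596. With only the groups of the comparison in the fit the counts were 66 for 5929745 at 12 h and 237 and 32 between the compounds. With the 0 h arrays as the reference they were 1219 and 4572 for 7606596 and 1541 and 4702 for 5929745, which adds the effect of time. With the replicate number as a replicate block they were 770 and 226 for 7606596, 183 and 223 for 5929745, 141 and 131 between the compounds, 20 and 14 for the time effects, and 1895 and 5553 for untreated seedlings. These numbers do not pair the arrays, as residual correlations over 21 pairs of groups had a median of 0.0105.

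Without single arrays the counts ran from 252 to 505 and from 62 to 310 for 7606596 at 3 h and 12 h, from 41 to 145 and from 39 to 317 for 5929745, and from 65 to 92 and from 28 to 188 between the compounds. The time effects ran from 7 to 17 for 7606596 and from 2 to 75 for 5929745, the shared calls from 34 to 103 at 3 h and from 16 to 92 at 12 h, and untreated seedlings at 3 h from 890 to 1172. The low ends came without 7606596 3 h replicate 2 (252, 65 and 7), untreated 12 h replicate 1 (62, 39, 7 and 16), 5929745 3 h replicate 2 (41, 2 and 34), 7606596 12 h replicate 1 (28) and 0 h replicate 1 (890).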

Other observations

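The list of late embryogenesis abundant (LEA) genes and the tests on it were chosen after such genes had been seen among the largest changes, and of these tests the one of seed storage genes had its bound written before its value was seen; the 18 further lists were drawn from the annotation before any fold change was seen.

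Among plastid-encoded ribosomal protein genes at 12 h, rps18 fell by 0.92 ± 0.14 with 5929745 (limma, adjusted p = 0.00256), and it was higher with 7606596 than with 5929745, but not without 7606596 replicate 1 (0.46, adjusted p = 0.607) or 5929745 replicate 1 (0.44, adjusted p = 0.267). In the direct comparison at 12 h 12 of 15 of these genes had positive differences, with 1 called higher (6 adjusted over the list alone) and a camera adjusted p of 3.68e-05 (adjusted p = 0.145 with an estimated correlation). All 10 genes of the plastid-encoded NDH complex had positive differences there, with 0 called by limma, 4 of unadjusted p under 0.05, 4 higher adjusted over the list alone and a camera adjusted p of 3.68e-05 (adjusted p = 0.145 with an estimated correlation). All 10 autophagy genes were on the same side, with a camera adjusted p of 3.92e-05 (adjusted p = 0.145 with an estimated correlation). The 1 called higher, ATG8E (0.59, adjusted p = 0.0496), lost its call without any 1 of the 4 arrays compared (0.50 to 0.68, adjusted p from 0.0712 to 0.477), with the replicate block (0.066), with median scaling (0.0741) and with an offset of 1 (0.0542). Of 18 wall-loosening genes 1 was called lower with 7606596 (4 adjusted over the list alone; camera adjusted p = 0.00165, adjusted p = 0.145 with an estimated correlation and 0.104 with the filter at the 60th percentile), and with 5929745 against untreated seedlings 2 rose (3 adjusted over the list alone; camera adjusted p = 0.0307, adjusted p = 0.456 with an estimated correlation, 0.288 with that filter and 0.171 without a filter). These 2 were EXLB1, not called without untreated replicate 1 (1.05, adjusted p = 0.123), and EXPA8, not called without 5929745 replicate 2 (0.79, adjusted p = 0.124) or untreated replicate 1 (0.80, adjusted p = 0.201) or 2 (1.02, adjusted p = 0.054). Of 11 CYP71B genes CYP71B24 was called higher in the direct comparison (camera adjusted p = 0.0101, adjusted p = 0.145 with an estimated correlation and 0.113 without a filter), but not without 7606596 replicate 1 (0.76, adjusted p = 0.263) or 5929745 replicate 1 (0.95, adjusted p = 0.0515) or 2 (0.80, adjusted p = 0.103).

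Of 9 amino acid breakdown genes 2 were called higher with 7606596 at 12 h than in untreated seedlings, and all 9 changes were positive (4 adjusted over the list alone; camera adjusted p = 2.29e-05, adjusted p = 0.214 with an estimated correlation). IVD lost its call without 7606596 replicate 1 (0.56, adjusted p = 0.224) or 2 (0.61, adjusted p = 0.067) or untreated replicate 1 (0.44, adjusted p = 0.415), and MCCA without untreated replicate 1 (0.68, adjusted p = 0.0555) or 2 (0.62, adjusted p = 0.065). Nuclear genes of thylakoid function had a camera adjusted p of 0.0181 with 7606596 at 12 h and 0.00633 with 5929745, where 2 of 27 fell (adjusted p = 0.214 and 0.136 with an estimated correlation). Of these 2, CCB3 was not called without 5929745 replicate 2 (-0.83, adjusted p = 0.108) or untreated replicate 1 (-0.86, adjusted p = 0.178), and NdhL not without these (-0.41, adjusted p = 0.213, and -0.62, adjusted p = 0.107) or untreated replicate 2 (-0.43, adjusted p = 0.236). In untreated seedlings at 12 h 7 of 10 genes of plastid RNA editing and processing rose, or 4 without untreated 12 h replicate 2 (camera adjusted p = 0.015, adjusted p = 0.415 with an estimated correlation). At 3 h with 7606596, 3 of 31 glucosyltransferase genes rose and 2 fell, but 1 rose and 0 fell without any 1 of the 4 arrays compared. Limma called 0 genes in the 6 comparisons of compounds for calmodulin-like proteins, chaperones, endoplasmic reticulum stress, iron regulators and stress U-box ligases, with at most 1, 3, 2, 2 and 2 of unadjusted p under 0.05.

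Most LEA genes that passed the filter were higher with 7606596 than with 5929745. Of 20 named in the annotation 13 passed it, and a filter on mean signal can keep a gene because it is high with 7606596. Of these 13, 11 were called higher at 3 h, 10 at 12 h and 0 lower at either time. The 3 h number was 7 and 6 without 7606596 replicates 1 and 2 and 7 without 5929745 replicate 2, and the 12 h number 2 without 7606596 replicate 1 and 4 without 5929745 replicate 1. Against 0 h their medians at 3 h and 12 h were 0.40 and 0.23 with 7606596, -1.1 and -1.49 with 5929745 and -0.83 and -1.2 in untreated seedlings, so the median lay above the 0 h level with 7606596 and below it in the other groups. The poly-A signals argue against the labelling difference seen in them as the cause, as it did not separate the 2 sets of treated arrays. Their mean log2 poly-A signals differed by 0.01 over both times and overlapped at each. They were 6.463 and 6.579 with 7606596 against 6.68 and 6.538 with 5929745 at 3 h, and 6.491 and 6.372 against 6.262 and 6.382 at 12 h. The median LEA difference of 1.84 adds no weight to this, as such genes were listed after their large changes had been seen. The 25S rRNA signals of these arrays differed at 3 h but overlapped at 12 h (409 and 320 with 7606596, 290 and 338 with 5929745), where the median LEA difference was 1.69. Ungerminated seeds among the seedlings of the 7606596 groups stay open. Seed storage and oil body genes had a median difference of 0.715, below 1.84 by more than the LEA spread of 0.895, which met the bound written before. That bound did not allow for the spread of the 2 storage genes themselves (SD 0.79), a criterion set after the value was seen: the oleosin gene AT2G25890 differed by 1.27 and PAP85 by 0.16, and 2 genes are too few to decide. Of 8 storage and oil body genes named in the annotation, only these 2 passed the filter on mean signal, and the others were not compared. A response to abscisic acid in the seedlings may contribute and stays open too, as the 7 measured vegetative abscisic acid genes had a median of 0.0662 with members on both sides and LTI30 alone called higher at 3 h.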
